A study of Mus musculus with 447 samples.

How the data were processed

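RNA was measured by Smart-seq3 in single GFP-positive cells sorted from fetal mouse pancreas at stage E15.5, with 1 cell per well of a plate. The 447 deposited samples are 447 cells of the genotypes Pdx1CreNeurod1OE (Neurod1OE, 212 cells) and Pdx1CreNgn3KONeurod1OE (Ngn3KO, 235 cells). Their titles carry a set number, 2 (117 Neurod1OE and 205 Ngn3KO cells) or 3 (95 and 30 cells), and each set was deposited as its own matrix. What the set number stands for is not stated, and it was treated as a batch.

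The values are raw read counts per gene and cell, deposited by the authors as whole numbers in sparse matrices without normalization. The submitters' processing notes list read trimming with Trimmomatic 0.39, alignment with HISAT2 2.1.0 to the mouse genome mm10, and counting with featureCounts 2.0.0. The gene annotation, the strand setting, the use of molecule barcodes and any cell filter applied before deposition are not stated. The matrices hold 40824 genes, of which 36411 (89.2%) have a symbol of the reference annotation used here for coordinates, and 92 ERCC spike-in sequences, which were left out of every total.

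Cells with at least 1000 detected genes were used, a limit that removed no cell. No doublet caller was run, because each well held 1 sorted cell. The median total was 572744 reads in Neurod1OE and 344128 in Ngn3KO cells of set 2, and 695079 and 728074 in set 3. To compare detected genes at equal depth, each cell was thinned at random to 165298 reads, the 10th percentile of all totals. Because the labels name no animal or litter, each genotype counted as 1 sample, cells were never used as replicates, and no p-value or standard error between genotypes was computed. Counts were summed over the cells of each genotype and set, giving 4 sums, and expressed as CPM (counts scaled to 1e+06 per sum by the plain total). The log2 ratio of Ngn3KO over Neurod1OE was taken within each set after adding 1 CPM. A gene counted as measured with at least 10 CPM and reads in at least 10% of cells in 1 genotype, and as higher or lower when at least 2-fold apart. The depth of the sums allows a 95% interval of 328 to 336 CPM for Neurod1 in Neurod1OE cells of set 2, while Neurog3, at 294 reads there, has 3.46 to 4.36 CPM. Intervals are exact Poisson or Clopper-Pearson intervals at 95% and cover counting error only. Where a count was 0, the limit given for it rests on 3 counts or cells.

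Hormone-high cells had at least 1000 CPM of a hormone, with Ins1 and Ins2 summed; cells with at least 2 hormones were counted over Gcg, insulin, Sst, Ppy and Ghrl, without Pyy. Cells of both genotypes and sets were clustered together: counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the set as batch, leaving out Neurog3, Neurod1, mitochondrial and sex genes, and 20 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 0 followed. A cluster was named after a marker list when at least 60% of the list stood at 50 CPM or more in the cluster and no list of another kind had more members among its 10 leading genes, the pan-endocrine, endocrine precursor and hormone cell lists being counted together. These naming limits were chosen after the data were seen. Ratios within a class were computed where each genotype had at least 10 cells of it in a set. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for scaling factors.

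Gene lists covered cell types (acinar, duct and trunk, endocrine progenitor and precursor, pan-endocrine, alpha, beta, delta, PP, epsilon, enterochromaffin, mesenchyme, endothelium, immune, erythroid, neural or Schwann, gut or stomach epithelium, hepatic, cycling) and programmes (secretory granule, islet transcription factors, Notch pathway, neuronal, DNA replication, immediate early and heat shock, unfolded protein response, epithelial junctions, epithelial to mesenchymal transition and delamination, sex genes). Each was summarised by the median log2 ratio of its measured members, given for at least 3 of them, and by the percentile of that median among 10000 random lists of equal size and matched expression. Some genes stand in several lists, so lists are not independent.

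Named genes were Neurog3, Neurod1, 8 hormone genes and 12 transcription factors whatever their values, up to 12 genes higher and 12 lower in both sets at 50 CPM or more, and up to 4 members of each list with the largest mean ratio. Predicted genes without a symbol, mitochondrial, ribosomal protein and haemoglobin genes were left out of this choice, and not every gene the rule names is given in the text. Comparisons, lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. Genes that the text calls chosen after their values were seen, up to 12 higher and 12 lower within a single set or within both subsets of set 2, lie outside this rule. So do the division of set 2 by 10 CPM of the predicted gene Gm12338 and the division of cells by sex from Xist and 4 Y-linked genes.

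The method was tested on simulated data with the cell numbers and depths of the 4 sums and 200 truly different genes: 97.0%, 86.6% and 85.1% of 3-fold differences were recovered in set 2, in set 3 and in both sets, and 100%, 98.5% and 98.5% of 4-fold ones. The different genes were drawn from those with Neurod1OE means at least 2-fold above the limit of 10 CPM in both sets. Recovery of genes between 10 CPM and that level was not tested. Simulated cells were drawn independently, without groups by embryo, sex or Gm12338. Both genotypes were given each gene's spread among Neurod1OE cells, limited at its extremes, so genes carried by few cells were not fully represented. Alternatives were TMM and DESeq2 scaling, the mean of the cells' CPM or of log2(CPM + 1) instead of sums, 0.1 or 10 CPM added, no gene filter or one of 50 CPM and 25% of cells, other cell filters, each gene's top cell left out, hormone reads left out of the total, 1.5-fold and 4-fold thresholds, pooled sets, other hormone levels, other clustering settings and another thinning depth. Added after the data were seen were Gm12338-positive, Gm12338-negative and female cells of set 2, set 2 without its acinar-like cell, male cells of set 3, and set 3 without its collagen-rich cells.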

Results

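The data were single-cell transcriptomes of fetal mouse pancreas at stage E15.5, made by Smart-seq3, a plate-based method that reads full-length polyadenylated RNA of 1 sorted cell per well. According to the series' design text, sorted GFP-positive cells came from mice in which a Pdx1-driven, tamoxifen-inducible Cre recombinase switched on NeuroD1, with or without deletion of floxed Neurog3 (Ngn3). NeuroD1 and Neurog3 are basic helix-loop-helix transcription factors of the endocrine pancreas, and Neurog3 normally precedes NeuroD1. The comparison asks whether NeuroD1 given to pancreatic progenitors acts in the same way when Neurog3 is deleted. Each of the 447 deposited samples was 1 cell: 212 were labelled Pdx1CreNeurod1OE, here Neurod1OE, and 235 were labelled Pdx1CreNgn3KONeurod1OE, here Ngn3KO. The sample titles divide the cells into a set 2 and a set 3, which were deposited as separate matrices. Set 3 held 95 Neurod1OE and 30 Ngn3KO cells, and the other 322 cells formed set 2. Wild-type cells, which would give the level without added NeuroD1, were not analysed here.

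The total count per cell ranged from 25769 to 2788066. Its median was 572744 in Neurod1OE and 344128 in Ngn3KO cells of set 2, and 695079 and 728074 in set 3. The median number of genes with at least 1 read was 8067 and 7448 in set 2, and 8179 and 7940.5 in set 3. After each cell was thinned to 165298 reads, these medians were 7223 and 7027 in set 2, and 7202.5 and 6832 in set 3; 2 and 31 shallower cells were left out in set 2, and 9 and 3 in set 3. The labels name no animal or litter, so each genotype counted as 1 sample, the sets were not taken as replicates, and no test between genotypes was made. Intervals are 95% exact Poisson intervals for reads and exact Clopper-Pearson intervals for shares of cells. They cover counting error only.

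The cells also fell into groups that the labels do not name. By Xist, transcribed from the inactive X chromosome of females, and 4 Y-linked genes, 64 Neurod1OE cells of set 2 were female, 50 male and 3 uncalled, whereas 0 Ngn3KO cells of set 2 were male and 7 were uncalled, the rest being female. In set 3, 29 Neurod1OE cells were female and 66 male, and all 30 Ngn3KO cells were male. In set 2, the predicted gene Gm12338 was below 10 CPM in 66 Neurod1OE and 97 Ngn3KO cells, and at or above it in the rest. The positive Neurod1OE cells were the 51 with the lowest numbers in their titles. The positive Ngn3KO cells also had the lowest title numbers, except for 5. Positive Neurod1OE cells were male where called (50 male, 0 female) and negative ones female (64 female, 0 male), while both Ngn3KO subsets held 0 male cells. Comparisons in set 2 are therefore also given within the Gm12338-positive and the Gm12338-negative subset, and comparisons in set 3 also within male cells. This division was chosen after the data were examined.

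The targeted genes were examined first, as a check on the labels. Neurog3 (chromosome 10, 62133090 to 62134763, plus strand, mm10; its coding sequence of 62133463 to 62134104 lies in exon 2) was scarce in set 2. It had 3.89 CPM in Neurod1OE cells (interval 3.46 to 4.36; 294 reads) and 3.06 CPM in Ngn3KO cells (2.69 to 3.47; 244 reads). A Neurog3 read was present in 32 Neurod1OE cells (27.4%, 19.5 to 36.4) and 43 Ngn3KO cells (20.98%, 15.6 to 27.2), and in 17.4% and 17.8% of the thinned cells. Thus the gene did not separate the genotypes in set 2. In set 3 Neurog3 stood at 17.8 CPM (16.9 to 18.8) in Neurod1OE and 3.72 CPM (2.96 to 4.61) in Ngn3KO cells, but 1 Neurod1OE cell held 69.9% of the Neurog3 reads of its genotype. The share of cells with a read was 21.1% (13.4 to 30.6) and 23.3% (9.93 to 42.3). Which part of the gene the floxed allele removes is not given in the sources used here, so the reads in Ngn3KO cells do not tell whether the deletion took place.

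Neurod1 (chromosome 2, 79452521 to 79456751, minus strand; coding sequence of 79453967 to 79455037 in exon 2), the overexpressed gene, was similar between the genotypes in set 2, with 332 CPM (328 to 336) in Neurod1OE and 292 CPM (288 to 296) in Ngn3KO cells. It differed in set 3, with 217 CPM (214 to 221) in Neurod1OE and 30.4 CPM (28.1 to 32.8) in Ngn3KO cells, where 1 cell held 54.6% of the reads. The median cell had 292 and 223 CPM in set 2, and 180.5 and 7.64 CPM in set 3. At least 10 CPM of Neurod1 was found in 100% and 98.5% of cells in set 2, and in 91.6% (84.1 to 96.3) of Neurod1OE but 40% (22.7 to 59.4) of Ngn3KO cells in set 3. The Neurod1 level of the set 3 cells labelled Ngn3KO therefore lay far below that of every other group, although their label names overexpression of this gene.

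**Figure D1:**
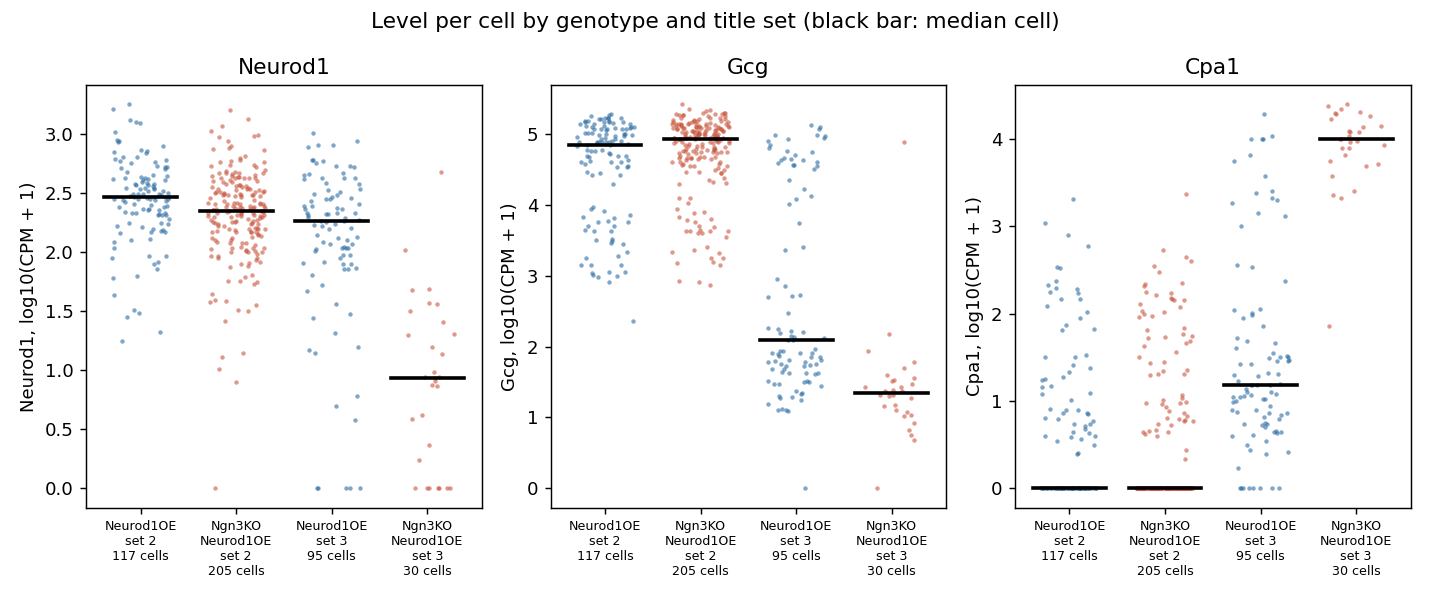
Level of Neurod1, Gcg and Cpa1 in each cell, as log10(CPM + 1) on the vertical axis, for the 322 cells of set 2 and the 95 Neurod1OE and 30 Ngn3KO cells of set 3; points are cells and the black bar is the median cell. Both genotypes of set 2 are high in Gcg, whereas Ngn3KO cells of set 3 are low in Neurod1 and Gcg and high in Cpa1.

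Glucagon-expressing cells made up nearly the whole of set 2 in both genotypes. Gcg, which encodes the alpha-cell hormone glucagon, reached 1000 CPM in 96.6% (91.5 to 99.1) of Neurod1OE and 98.5% (95.8 to 99.7) of Ngn3KO cells. Within the Gm12338-positive subset these shares were 92.2% and 98.1%, and within the negative subset 100% and 98.97%. The same cells were rich in peptide YY (Pyy, 97.4% and 93.7% of cells), and part of them in pancreatic polypeptide (Ppy, 24.8% and 24.4%, with 27.5% and 37.96% in the positive and 22.7% and 9.28% in the negative subset) and ghrelin (Ghrl, 8.55% and 11.7%). The insulin genes Ins1 and Ins2 together reached 1000 CPM in 5 Neurod1OE (4.27%, 1.40 to 9.69) and 10 Ngn3KO cells (4.88%, 2.36 to 8.79). Somatostatin (Sst) reached it in 0 Neurod1OE cells, which allows a share of up to 2.56%, and in 2 Ngn3KO cells (0.976%, 0.118 to 3.48). Of Gcg, insulin, Sst, Ppy and Ghrl, a set that leaves out Pyy, at least 2 passed this level in 30.8% (22.6 to 39.97) of Neurod1OE and 38.5% (31.8 to 45.6) of Ngn3KO cells. That share differed in the positive subset (31.4% against 50.9%) and went the other way in the negative subset (30.3% against 24.7%).

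In set 3 the genotypes differed in cell composition. Gcg reached 1000 CPM in 32 of 95 Neurod1OE cells (33.7%, 24.3 to 44.1) and 1 of 30 Ngn3KO cells (3.33%, 0.0844 to 17.2). Cpa1, which encodes the digestive enzyme carboxypeptidase A1 of acinar cells and was chosen for this count after its values were seen, reached it in 16 of 95 (16.8%, 9.94 to 25.9) and 29 of 30 cells (96.7%, 82.8 to 99.9). Pyy passed the level in 51.6% of Neurod1OE and 3.33% of Ngn3KO cells, Ppy in 11.6% and 0%, and Ghrl in 11.6% and 3.33%; 0 of 30 cells allows a share of up to 10.0%. Among male cells of set 3, the Gcg share was 40.9% in Neurod1OE (27 of 66) and 3.33% in Ngn3KO cells, and the Cpa1 share 10.6% and 96.7%.

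**Figure D2:**
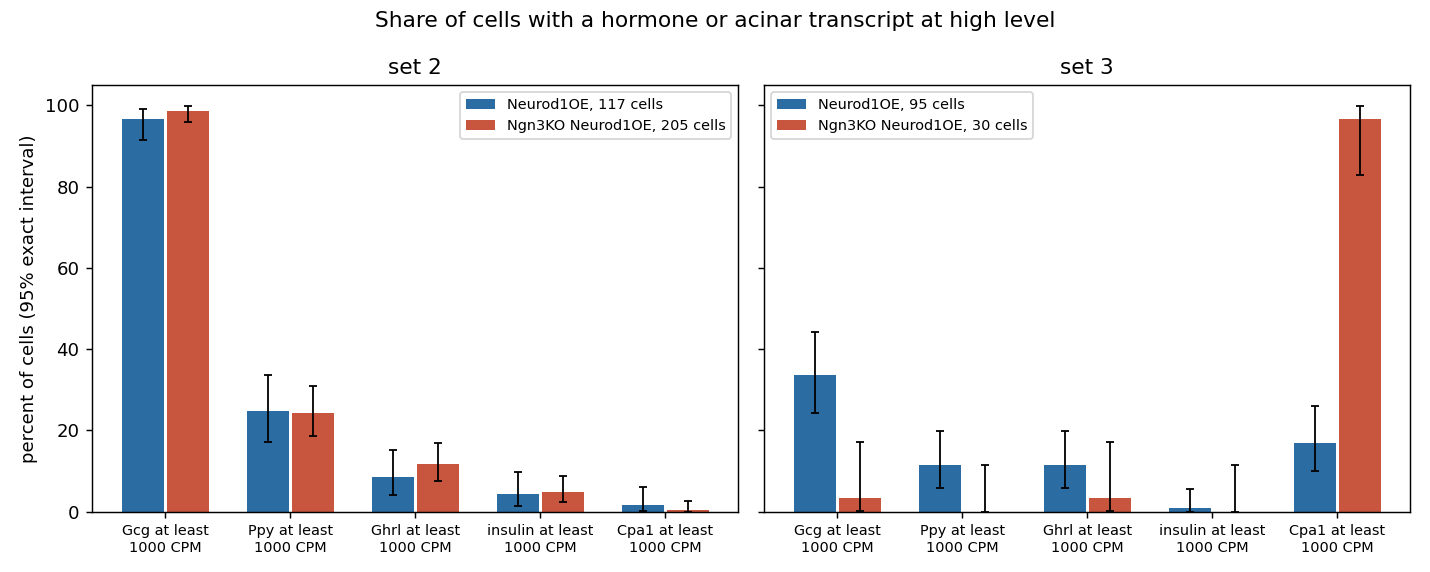
Percent of cells (vertical axis) at or above 1000 CPM of Gcg, Ppy, Ghrl, insulin (Ins1 and Ins2 together) and Cpa1 in Neurod1OE and Ngn3KO cells of set 2 (left) and set 3 (right); error bars are 95% exact intervals for counting error. The Gcg share is 96.6% and 98.5% in set 2, and the Cpa1 share is 16.8% and 96.7% in set 3.

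Clustering of all cells without Neurog3, Neurod1 and the sex genes gave 13 clusters. Cluster 9 was acinar-like, with 12 of 13 acinar markers at or above 50 CPM; it also carried the collagen gene Col3a1 among its leading genes. Clusters 0 to 3, 5 to 8 and 11 were endocrine-like, each with 16 of 16 pan-endocrine markers. Clusters 4, 10 and 12 stayed unnamed, because cell cycle, hepatic or duct markers outnumbered endocrine ones among their leading 10 genes. They too passed the limit for pan-endocrine markers, with 16 of 16 in clusters 4 and 10 and 11 of 16 in cluster 12. The unnamed share is therefore not a share of cells without endocrine markers. The marker level for naming was set after the data were seen. In set 2, 90.6% (83.8 to 95.2) of Neurod1OE and 90.2% (85.3 to 93.9) of Ngn3KO cells were endocrine-like, and 8.55% and 9.76% unnamed. In set 3, 44.2% (34.02 to 54.8) of Neurod1OE cells and 0 of 30 Ngn3KO cells were endocrine-like, 13.7% (7.49 to 22.3) and 96.7% (82.8 to 99.9) were acinar-like (2.11% and 63.3% at clustering resolution 2), and 42.1% and 3.33% stayed unnamed. The acinar-like share of Neurod1OE cells in set 3 was 31.03% (9 of 29) among female and 6.06% (4 of 66) among male cells. Cluster 9 held mostly cells of 1 genotype and set, and the genes that define it differed between the genotypes. The shares at 1000 CPM of Gcg and Cpa1 need no clustering.

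Within set 2, most endocrine genes were at similar levels in the genotypes. All 16 measured pan-endocrine genes lay within 2-fold (median log2 ratio of Ngn3KO over Neurod1OE 0.07). Among them were Scgn (588 CPM in Neurod1OE and 561 CPM in Ngn3KO cells), Scg2 (475 and 489 CPM) and Pcsk1n (468 and 411 CPM). The 10 alpha genes had a median of 0.18, with Gcg at 66129 and 85491 CPM and the proprotein convertase Pcsk2 at 2113 and 2090 CPM. The islet transcription factors Isl1 (844 and 750 CPM), Pax6 (664 and 615 CPM), Insm1 (143.2 and 149.4 CPM), Nkx2-2 (110.6 and 117.2 CPM) and Rfx6 (100.9 and 107.9 CPM) differed by less than 2-fold, and 0 of 17 measured islet transcription factors were past 2-fold. Median log2 ratios of the secretory granule, endocrine precursor and endocrine progenitor lists were 0.04, 0.08 and -0.08.

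Members of some lists did differ in set 2. Of 11 measured beta-cell genes, 6 were at least 2-fold higher in Ngn3KO cells and 0 lower (list median 1.12, percentile 100 among 10000 random lists of matched expression). With each cell weighted equally the list median was 0.20. From summed counts the list median was 1.62 in the Gm12338-positive but 0.15 in the negative subset. Ins2 stood at 153.1 CPM in Neurod1OE and 4045 CPM in Ngn3KO cells, Ins1 at 95.8 and 781 CPM, and Nnat at 154.9 and 1485 CPM. The 10 Ngn3KO cells above 1000 CPM held 96.5% of the insulin reads of their genotype, and the median cell had 75.1 and 101.7 CPM of insulin. In the Gm12338-negative subset Ins1 and Ins2 had log2 ratios of -0.08 and 0.76, against 3.33 and 4.87 in the positive subset. Sst was at 11.3 and 272 CPM, and 1 Ngn3KO cell held 88.4% of the reads. Ghrl was at 533 and 1193 CPM, a log2 ratio of 1.16 (0.70 in the positive and 1.52 in the negative subset). Among genes chosen after their values were seen, the neuropeptide gene Npy stood at 7.27 and 269 CPM, and the fetal serum protein gene Afp at 14.9 and 79.4 CPM. Afp differed alike in both subsets, with log2 ratios of 2.12 and 2.51.

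Lower in Ngn3KO cells of set 2 were 5 of 6 measured acinar genes, with a list median of -2.00 (percentile 0). Cpa1 stood at 118.7 CPM in Neurod1OE and 28.7 CPM in Ngn3KO cells. The only acinar-like cell of set 2 was a Neurod1OE cell, and with its top cell left out the log2 ratio of Cpa1 was -0.81. Without the acinar-like cell the list median was -0.28. Immediate early and heat shock genes, which respond to stimulation and handling, had a median of -0.74 (percentile 0), and -0.85 and -0.55 in the positive and negative subset (percentiles 0 and 0.12), but 0.26 among female cells of set 2, which are Gm12338-negative in Neurod1OE and of both subsets in Ngn3KO; 1 of 7, Ier2, was past 2-fold (109.5 and 41.3 CPM), and Junb (178.1 and 107.98 CPM), Fos (177.4 and 105.9 CPM) and Egr1 (202.8 and 150.4 CPM) were below it. The 7 cycling genes had a median of -0.62 (percentile 0), with 0 past 2-fold, but -0.17 with each cell weighted equally. In endocrine-like cells, a class that leaves out cluster 4 but keeps cluster 5, both led by cell cycle genes, Mki67, Top2a, Ccna2, Cenpf, Birc5 and Cdk1 had log2 ratios of 0.37 to 1.02. Duct and trunk genes had a median of -0.49 (percentile 0) with 3 of 11 past 2-fold, among them Spp1, encoding osteopontin (221 and 30.3 CPM), and Anxa2 (21.2 and 1.36 CPM). The list median was -0.07 without the 2% of cells with the highest totals and the 2-hormone cells, and the ratio of Anxa2 in endocrine-like cells was -0.73 without its top cell. The Notch target Hes1 stood at 21.3 and 6.79 CPM (in endocrine-like cells a log2 ratio of -1.05, or -0.50 without its top cell), and the Notch list at a median of -0.27 (percentile 6.33), with 0.24 in the positive and -0.74 in the negative subset.

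In all, 0.859% of the 10011 genes measured were at least 2-fold higher (86 genes) and 1.67% at least 2-fold lower in Ngn3KO cells of set 2. In counts simulated at these cell numbers and depths, 1.70% of 9691 unchanged genes passed 2-fold in set 2 in either direction. Both genotypes had the spread of the Neurod1OE cells there, limited at its extremes, so this share may be too low for genes carried by few cells. Within the positive subset 3.37% were higher and 4.37% lower, and within the negative subset 1.43% and 3.53%. Only 13 genes were at least 2-fold higher and 39 lower in both subsets, where independent calls would give 2.49 and 7.39, and 32 went opposite ways, where they would give 9.65. Between the subsets of a genotype more genes differed than between the genotypes: 719 were higher and 740 lower in the positive subset of Neurod1OE cells, and 675 and 477 in that of Ngn3KO cells.

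In set 3 the endocrine programme stood far lower, and the acinar programme higher, in cells labelled Ngn3KO. The median of all 10482 measured genes was itself at a log2 ratio of -0.56, because plain totals were used; with TMM scaling it was -0.06 and with DESeq2 size factors 0.05, and list values are to be read against it. All 16 pan-endocrine genes were at least 2-fold lower (median -3.05, percentile 0). Scgn stood at 297 CPM in Neurod1OE and 3.49 CPM in Ngn3KO cells, Scg2 at 331 and 5.53 CPM, and Pcsk1n at 1062 and 39.2 CPM. All 10 alpha genes were lower (median -2.79, percentile 0), with Gcg at 19802 and 2713 CPM and Pcsk2 at 1066 and 49.9 CPM; 1 Ngn3KO cell carried most Gcg reads, and without each gene's top cell the alpha median was -6.05. Hormone genes followed: Ppy was at 2343 and 15.4 CPM, Pyy at 7588 and 232 CPM, Iapp at 1738 and 48.6 CPM, Ghrl at 1143 and 89.9 CPM, Sst at 316 and 1.59 CPM, Ins2 at 137.2 and 2.67 CPM and Ins1 at 58.9 and 0.0906 CPM.

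Of 19 islet transcription factors measured in set 3, 16 were at least 2-fold lower and 0 higher in Ngn3KO cells (median -2.14, percentile 0). Pax6 stood at 327 and 11.8 CPM, Isl1 at 396 and 40.2 CPM, Fev at 110 and 2.08 CPM, Pax4 at 32.7 and 3.13 CPM, Rfx6 at 133.9 and 19.9 CPM, Insm1 at 139.2 and 38.6 CPM and Nkx2-2 at 93.95 and 34.9 CPM. Pdx1 (18.4 and 14.2 CPM) and Nkx6-1 (36.5 and 18.5 CPM) were less than 2-fold apart. All 7 endocrine precursor genes (median -3.21), 10 of 13 secretory granule genes (median -3.21) and 8 of 10 neuronal genes (median -2.18, percentile 0.05), such as Gap43 (75.5 and 3.72 CPM) and Tubb3 (84.9 and 19.5 CPM), were lower. Of 9 endocrine progenitor genes 4 were lower and 1 higher: Btbd17 stood at 85.6 and 4.17 CPM, the Notch modifier Mfng at 48.6 and 3.58 CPM, and the cell cycle inhibitor Cdkn1a, the higher one, at 373 and 757 CPM. The list median was -0.34 (percentile 67.03).

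Of 12 acinar genes, 11 were at least 2-fold higher and 0 lower in Ngn3KO cells of set 3 (median 2.81, percentile 100). Colipase (Clps) stood at 3509 CPM in Neurod1OE and 36151 CPM in Ngn3KO cells, Cpa1 at 1315 and 10606 CPM, bile salt lipase (Cel) at 210 and 2360 CPM and the acinar transcription factor gene Ptf1a at 17.3 and 70.01 CPM. Sox9, a factor of progenitors and ducts, differed little (126.2 and 143.3 CPM), and the duct and trunk list had a median of -0.02 with 5 of 12 members higher and 4 lower. The cycling list had a median of 0.68 (percentile 99.8) with 0 of 7 past 2-fold, DNA replication genes 0.46 (percentile 100) and unfolded protein response genes 0.51 (percentile 98.4), with the secretory-pathway regulator Xbp1 at 180.9 and 376 CPM. Epithelial junction genes had a median of 0.50 (percentile 99.5); Cdh1, encoding E-cadherin, was at 81.2 and 243 CPM, whereas the tight junction gene Tjp1 was at 90.9 and 34.8 CPM. Genes of epithelial to mesenchymal transition and delamination had a median of -1.90 (percentile 1.72). Mesenchyme genes had a median of 3.20 (percentile 100), but 2 Ngn3KO cells held 99.2% of the Col1a1 and 99.5% of the Col3a1 reads, and without these cells the median was -1.89.

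**Figure D3:**
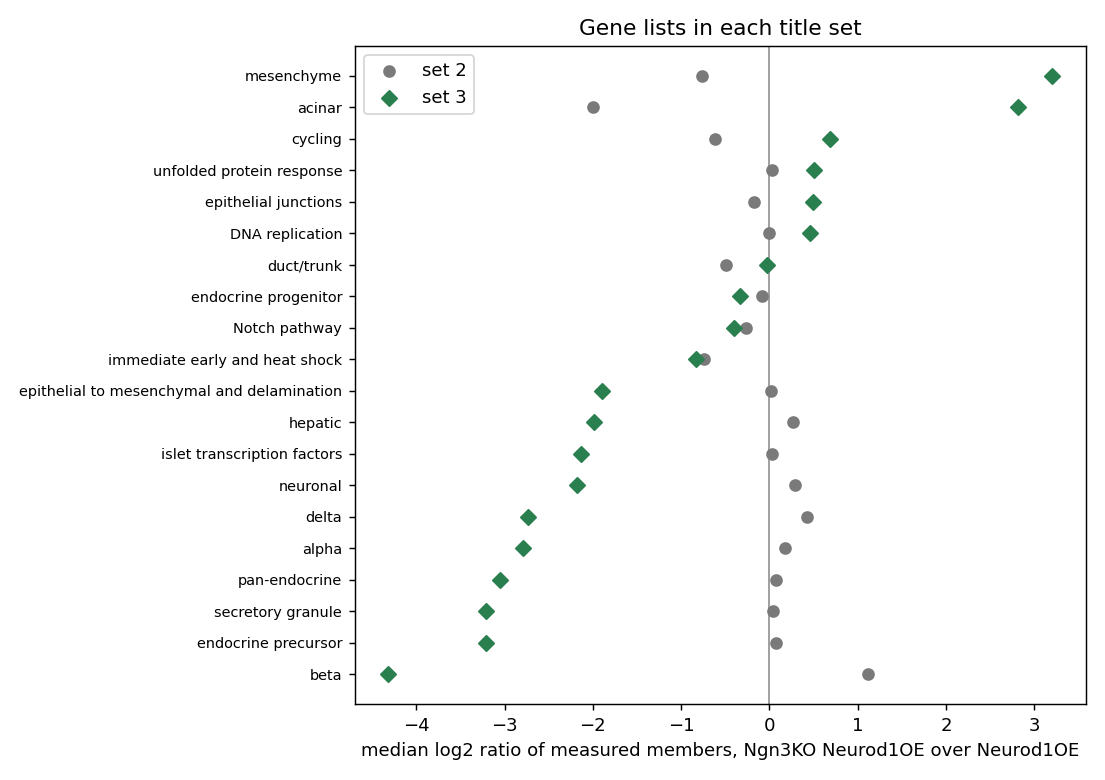
Median log2 ratio of Ngn3KO over Neurod1OE (horizontal axis) of the measured members of each fixed gene list, in set 2 (circles) and set 3 (diamonds). In set 3 the pan-endocrine, endocrine precursor, alpha, beta, delta, secretory granule and islet transcription factor lists lie between -4.32 and -2.14, the endocrine progenitor list at -0.34 and the acinar list at 2.81; in set 2 the pan-endocrine, alpha and islet transcription factor lists lie near 0.

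In total, 625 genes were at least 2-fold higher and 3333 lower in Ngn3KO cells of set 3, a share of 15.8% higher among those past 2-fold. With TMM scaling the counts were 1372 and 1923 (41.6% higher), and with DESeq2 size factors 1581 and 1722 (47.9% higher). Among male cells the counts were 866 and 3696, and the pan-endocrine and acinar medians -3.25 and 3.80. In simulated counts at the cell numbers of set 3, 1170 of 10349 unchanged genes passed 2-fold.

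The sets gave different answers, and few genes differed alike in both. Of 9478 genes measured in both sets, 8 were at least 2-fold higher in Ngn3KO cells in both and 26 lower in both, where independent calls would give 1.74 and 41.9. Another 59 went opposite ways: 27 were higher in set 2 and lower in set 3, where independent calls would give 17.1, and 32 lower in set 2 and higher in set 3, where they would give 4.27. The correlation of the log2 ratios between sets was r = -0.13 across genes, which are not independent replicates. Among genes at or above 50 CPM in both sets, 2 named genes were lower in both. Spp1 (chromosome 5, 104435118 to 104441050) had log2 ratios of -2.83 and -4.02, and Efna5 (chromosome 17, 62604184 to 62881317), which encodes the Eph receptor ligand ephrin-A5, -1.06 and -3.60. Spp1 was lower in both subsets of set 2 (-2.30 and -3.19), but Efna5 only in the negative one (-0.33 and -1.50). Within classes and without its top cell, the Spp1 ratio was -0.06 in endocrine-like cells of set 2 and 0.05 in acinar-like cells of set 3. The 23 cells of cluster 12, all Neurod1OE cells of set 3, had a mean of 2845 CPM of Spp1. Its ratio in set 3 thus cannot be separated from cluster makeup. No named gene above this level was higher in both sets. At lower levels, and chosen after their values were seen, the activin receptor gene Acvr1c was higher in both (log2 ratios 1.29 and 1.52), and the transcription factor genes Ebf1 (-1.50 and -5.31) and Id1 (-1.28 and -2.40) were lower. In set 2, Id1 was past 2-fold only in the positive subset (-1.77, against -0.57 in the negative one). In the simulated counts 13 of 9133 unchanged genes passed 2-fold alike in both sets.

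Values within a cell class remove differences in the shares of the named classes, but not those in the makeup of a class. In endocrine-like cells of set 2 (90.6% and 90.2% of the genotypes' cells), 1.10% of 9895 measured genes were at least 2-fold higher and 1.36% lower in Ngn3KO cells. Ins2 (111.4 and 4528 CPM) and Nnat (179.1 and 1657 CPM) were again higher (few cells carry the insulin reads of set 2, as given above), whereas Neurod1 (328 and 297 CPM), Pax6 (688 and 639 CPM) and Cpe (2530 and 2406 CPM) were similar. Ier2 (114.8 and 42.5 CPM) and the complement factor gene Cfi (95.01 and 35.1 CPM) were lower. Spp1 stood at 93.2 and 25.5 CPM there, but at a log2 ratio of -0.06 once its top cell was left out. Only the acinar-like class had at least 10 cells of each genotype in set 3 (13 Neurod1OE and 29 Ngn3KO cells). This class was not stable: at clustering resolution 2, 2.11% of Neurod1OE and 63.3% of Ngn3KO cells of set 3 were acinar-like. The values within it may therefore compare cells of different makeup. There 662 of 9458 genes were at least 2-fold higher and 1639 lower in Ngn3KO cells. Digestive enzyme genes were higher, with Clps at 8923 and 37460 CPM, Ctrb1 at 6483 and 23360 CPM, Cel at 582 and 2446 CPM and Cpa1 at 4859 and 10990 CPM. The acinar transcription factors Rbpjl (387 and 360 CPM), Bhlha15 (163.5 and 190.2 CPM) and Ptf1a (56.7 and 72.6 CPM) were less than 2-fold apart. Cell cycle genes were lower or similar, with Cdk1 at 426 and 132.6 CPM and Top2a at 457 and 230 CPM. Neurod1 was low in these cells of both genotypes (22.01 and 14.3 CPM). Endocrine genes, lower in Ngn3KO cells of set 3 as a whole, were not uniformly lower within this class. Chga (60.2 and 311.6 CPM), Cpe (90.1 and 206.7 CPM) and Pam (105.6 and 293.6 CPM) were higher in Ngn3KO cells. Nkx2-2 (19.3 and 32.9 CPM) was less than 2-fold apart, and Gcg (52.3 and 25.5 CPM) was lower. Of the acinar-like Neurod1OE cells 9 were female, and all 29 Ngn3KO cells were male.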

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

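All tests of explanations in this part were chosen after the results were seen. Log2 ratios are of Ngn3KO over Neurod1OE. The 6 differences between sets given here stood out because the ratios of set 2 and set 3 had opposite signs, each at least 2-fold; these differences between sets were not tested.

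The first pattern is the genotype difference of set 3, absent from set 2: the acinar list had a median log2 ratio of -2.00 in set 2 and 2.81 in set 3 (difference 4.80; without the 1 acinar-like cell of set 2 the median there was -0.28, short of 2-fold), and the beta list 1.12 and -4.32 (difference -5.44). Against embryo sex as its cause, 6.06% (1.68 to 14.8) of the male Neurod1OE cells of set 3 were acinar-like, where 96.7% of the male Ngn3KO cells were. For the Ngn3KO genotype alone as the cause, 1.46% (0.303 to 4.22) of the Ngn3KO cells of set 2 were under 1000 CPM of Gcg. This shows only that cells low in Gcg did not go with this label in set 2. It cannot decide on the genotype, because the Neurog3 reads do not tell whether the deletion took place. Cells at 1000 CPM of Gcg also made up 96.6% of Neurod1OE cells in set 2, against 33.7% in set 3. Acinar cells without Neurod1 overexpression in the sorted gate cannot be told apart from other acinar cells: the acinar-like Ngn3KO cells had 4.61% of the Neurod1 CPM of endocrine-like cells in set 3, but Neurod1 is itself an endocrine gene, and acinar-like Neurod1OE cells had 7.10%. This and the Ngn3KO genotype stay open beside a mislabelled sample and differences between embryos or in the induction of Cre, for which the labels give no test.

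The second pattern is the split of set 2 by Gm12338. Against embryo sex as the whole cause, the ratios of positive over negative cells in the 2 genotypes had r = 0.520 across genes without the sex genes, although both Ngn3KO subsets held 0 male cells. A library or plate batch is a candidate explanation: 19 ribosomal protein pseudogenes, which share reads with their parent genes, had a median log2 ratio of positive over negative of -1.32 in Neurod1OE and -1.03 in Ngn3KO cells. Such pseudogenes, as Rpl21-ps15 and Rpl9-ps6, stood among the most lowered genes of this same split. The medians therefore describe the split and are no separate test of a batch. Litter or embryo stays open, as the labels name neither.

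The last pattern is insulin in set 2, where Ins1 and Ins2 had log2 ratios of 3.01 and 4.71, against -5.78 and -5.23 in set 3 (differences -8.79 and -9.95). The Ngn3KO genotype alone as its cause stays open: in Gm12338-negative cells the ratio was -0.082 for Ins1 but 0.76 for Ins2, against 3.33 and 4.87 in positive cells. Among positive cells, the called Neurod1OE cells were male (50 male, 0 female) and 0 Ngn3KO cells were male. Embryo sex therefore cannot be told apart from genotype in that subset. The higher insulin sum of Ngn3KO cells in set 2 rested on few cells. The 10 Ngn3KO cells at or above 1000 CPM held 96.5% of the insulin reads of their genotype. The 5 such Neurod1OE cells held 54.5% of theirs, and the median cell's insulin had a log2 ratio of 0.43. Whether these few cells reflect the genotype, embryo sex or chance sampling of rare cells was not tested.

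Sst had log2 ratios of 4.46 in set 2 and -6.94 in set 3, a difference of -11.40. Ghrl had 1.16 and -3.65, a difference of -4.81. Set 2 had 24 reads of ERCC spike-in sequences over all cells, which no comparison used, more than the 3 reads that a count of 0 allows.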

How the results depend on the processing

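The settings by Gm12338, by sex, without the collagen-rich cells and without the acinar-like cell were chosen after the data were seen. Of 386 values of the main results under other settings, 289 stayed within their counting interval, within the spread of their list or, for gene counts, within 1.5 times the count, 97 moved further and 0 went from at least 2-fold to the opposite sign. Of 2770 ratios of named genes, 1054 stayed, 1695 moved and 21 went from at least 2-fold to the opposite sign; of 484 other list medians and hormone shares, 429, 54 and 1 did so. Sign changes of values less than 2-fold apart count as stayed or moved. Leaving out the cell filter or asking for 2500 genes removed no cell and tests nothing. Values of these settings are nevertheless counted among those that stayed, except for the ratios of named genes, where they were not used. Among the main results, only list medians could be counted as going to the opposite sign. The pan-endocrine median ranged from -0.07 to 0.13 in set 2 and from -4.21 to -2.46 in set 3, the acinar median from -2.72 to -0.26 and from 2.65 to 6.68, and the beta median from 0.15 to 1.62 and from -4.58 to -1.41. No paired analysis was possible because the last numbers in the titles only name cells and the labels name no animal to pair; ratios were taken within each set, and a fit of genotype and set over the 4 sums was not made, since sets were not taken as replicates. Depth limits Neurog3, with 294 and 244 reads in set 2, and a gene carried by few cells rests on those cells. For values that moved, the cause was not tested, except where a threshold, filter or cell choice sets the number by construction.

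Shares are in percent of measured genes, higher and then lower in Ngn3KO cells where both are given. With TMM scaling they were 13.1 and 18.4 in set 3 (5.96 and 31.8 in the report's setting), and 0.161 lower in both sets (0.274); with DESeq2 size factors 15.1 and 16.5, and 0.140. With the mean of the cells' CPM 0.975 were lower in set 2 (1.67). With the difference of mean log2(CPM + 1), 0.0211 were higher in both sets (0.0844), 0.0999 and 0.709 higher and lower in set 2 (0.859 and 1.67) and 15.35 higher in set 3; the acinar median of set 3 was 6.68. With 10 CPM added they were 0.0211 and 0.0317 in both sets, 0.2497 and 0.3396 in set 2 and 3.49 and 19.3 in set 3. Without a gene filter they were 0.145 and 0.684 in both sets, 1.87 and 2.54 in set 2 and 4.90 and 24.6 in set 3. At 50 CPM and 25% of cells they were 0.0258 and 0.0516 in both sets, 0.389 and 0.389 in set 2 and 6.40 and 26.8 in set 3. At 1.5-fold they were 0.253 and 2.796 in both sets, 3.39 and 7.22 in set 2 and 11.4 and 49.2 in set 3; at 4-fold 0 and 0.0211, 0.170 and 0.230, and 1.49 and 11.2. Without the top 2% of cells and 2-hormone cells 0.657 were lower in both sets and 1.61 higher in set 2. Without each gene's top cell 0.0441 were higher in both sets, 0.973 lower in set 2 and 0.714 lower in endocrine-like cells of set 2 (1.36), and the alpha median of set 3 was -6.05. With the sets pooled 0.893 and 2.16 passed.

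In Gm12338-positive cells the shares were 0.169 and 1.13 in both sets, 3.37 and 4.37 in set 2, and 3.80 and 4.46 in endocrine-like cells. In negative cells they were 0.0532 and 0.713, 1.43 and 3.53, and 2.42 and 2.70, and the alpha median of set 2 was -0.028. In female cells of set 2 they were 1.91 and 2.78. In male cells of set 3 the acinar median was 3.80, and without collagen-rich cells the mesenchyme median was -1.89. Male cells gave no value within the acinar-like class, which held 4 male Neurod1OE cells, and the delta and sex gene lists gave no median in negative cells, with under 3 members measured.

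Cells with Neurog3 were 17.4% of Neurod1OE cells in set 2 after thinning. At 10 CPM they were 9.40% and 8.42% of Neurod1OE cells in sets 2 and 3, and 6.83% and 3.33% of Ngn3KO cells; cells with Neurod1 were 40% of Ngn3KO cells in set 3. As mean of the cells' CPM, Neurog3 was 43.9 in Neurod1OE cells of set 3 and 3.84 in Ngn3KO cells of set 2, and Neurod1 369.8 and 234.5 in Neurod1OE cells of sets 2 and 3 and 280.7 in Ngn3KO cells of set 2. At 100 CPM, 100% of both genotypes in set 2 and 50.5% of Neurod1OE cells in set 3 had Gcg, and 41.03%, 51.2% and 10.5% insulin; at 10000 CPM, 71.8% and 85.9% in set 2 had Gcg, and 0.855%, 1.46% and 0% insulin. At clustering resolution 2, 0% and 2.11% of Neurod1OE cells in sets 2 and 3 and 63.3% of Ngn3KO cells in set 3 were acinar-like; with 1000 variable genes 76.9% and 73.2% of cells in set 2 were endocrine-like. Thinned to the 5th percentile, cells had 6861 and 6671 genes in set 2 and 6884 and 6537 in set 3.

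These log2 ratios have the opposite sign to a value of at least 2-fold in the report's setting. In Gm12338-negative cells of set 2 they were -0.082 for Ins1, -0.19 for Sst, -0.23 for Xist and -1.97 for P2ry1, and in positive cells -0.30 for Cck, 1.34 for Ctrb1 and 0.0026 for Pnliprp1. In female cells of set 2 they were 0.097 for Dcn, 0.27 for Eif2s3y, 0.22 for Ddx3y and 0.11 for Uty. With the mean of the cells' CPM Cel was at 0.23 in set 2. With the difference of mean log2(CPM + 1), Cck was at -0.35 and Pnliprp1 at 0.058 in set 2, and Anxa2 at 0.77, Sparc at 0.34 and Col1a2 at -0.56 in set 3. Without collagen-rich cells of set 3, Dcn was at -1.14, Col1a2 at -1.89, Col3a1 at -0.12 and Col1a1 at -0.32.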

Other observations

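The genes and clusters in this part were chosen after their values were seen, and no explanation was tested for them. Of the gene lists, those not given above had these median log2 ratios of Ngn3KO over Neurod1OE in set 2 and set 3: delta 0.43 and -2.74, hepatic 0.27 and -1.98, and sex genes -4.37 and -0.82. In set 2 alone they were 0.29 for neuronal, 0.02 for epithelial to mesenchymal transition and delamination, 0.03 for unfolded protein response, -0.18 for epithelial junction, -0.01 for DNA replication and -0.77 for mesenchyme genes. In set 3 alone they were -0.84 for immediate early and heat shock and -0.40 for Notch genes. The PP, epsilon, enterochromaffin, neural or Schwann, erythroid and gut lists had under 3 measured members in each set and no median. In set 2 their members past 2-fold were 1 higher for epsilon and 0 for the others; in set 3, 2 PP, 2 epsilon, 2 neural and 1 enterochromaffin gene were lower, 2 gut genes higher and 0 erythroid genes past 2-fold. Of the endothelium and immune lists, 0 members were measured in either set.

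Clusters 10, 11 and 12 consisted almost wholly of Neurod1OE cells of set 3, so their genes cannot be separated from that set and genotype. Cluster 12 (23 cells, all of this group) had a median cell of 355.8 CPM of Spp1 against 10.9 in the other cells, 141.6 CPM of Sox9 against 4.79, 286.7 CPM of Btbd17 against 5.99 and 311.6 CPM of Hes6 against 78.7, but 27.7 CPM of Epcam. A Neurog3 read was present in 4 of its cells, with up to 3053 CPM. Cluster 11 (12 of 13 cells of this group) had 230.0 CPM of Fev against 43.4, with Gcg at 54.8 CPM. Cluster 10 (14 of 16 cells) had 797 CPM of Cartpt against 5.97, 353.7 CPM of Gal against 6.01 and 52660 CPM of Ttr against 4565, with Gcg at 41130 CPM.

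Between the Gm12338 subsets of set 2, log2 ratios of positive over negative in Neurod1OE and Ngn3KO cells were 2.09 and 2.31 for Txnip and 1.958 and 2.356 for Malat1, and -2.00 and -2.18 for Ttr, -2.09 and -2.48 for Afp and -2.63 and -3.48 for Cartpt.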
